A study of Gallus gallus with 9 samples.

How the data were processed

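RNA sequencing libraries of sorted GFP-positive cells from 5 PtcDLoop2 and 4 control GFP chick embryos were compared. Per the labels' protocols each embryo was sorted on its own, and the series text calls the libraries separate biological replicates. The protocol speaks of 5 sorted embryos in each group, and 4 control libraries are used here. Tissue behind the heart was dissected from both sides of the embryo and dissociated with trypsin before the sort. The submitters' processing notes name cutadapt 1.8.3, STAR 2.4, HTSeq 0.6.1p1, DESeq2 and DESeq and the genome build galGal4, without giving their settings.

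The deposited expression table holds 12155 genes in 9 columns of counts that the authors had divided by a size factor per library and rounded to 1 decimal, as the values show. The deposited comparison table gives, per gene, a mean signal over the libraries in normalized counts, a log2 fold change of PtcDLoop2 against control, a p-value and an adjusted p-value. Its mean signal differed from the row means of the deposited expression table by 0.0256 normalized counts on average. In the authors' deposited table the genes marked stringent have adjusted p-values up to 0.041 and absolute log2 fold changes from 1.38, and those marked permissive have adjusted p-values up to 0.0893. 5 genes were at 0 in all libraries.

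Values in each library were whole multiples of a fixed step, so the step was fitted and whole reads were recovered. All values lay within 0.06 normalized counts of a whole number of reads. The recovered totals were between 10388989 and 13517164 reads per library, so counting error was small beside the spread between embryos for the named genes, which had at least 114 reads in every library. The plan made before the data were examined named limma-trend on log2(value + 1) for a table of normalized counts, also where whole reads can be recovered, in place of a count model, and it was the main test. The recovered reads would allow a count model. DESeq2, edgeR and surrogate variables with sva were not run. The columns of the deposited table had not been registered as count data, since each of its lines is quoted as a whole. This did not bar such fits, as the recovered reads were used for limma-voom.

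Genes with a value of at least 10 in at least 4 libraries were tested, which left 9621. The model had the group as its only term. Limma 3.58.1 in R 4.3.3 was used with a mean-variance trend and robust empirical Bayes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are differences between group means of log2(value + 1). For low genes these can lie below or above those of the authors' deposited table. Named genes were to be listed by p if fewer than 10 genes passed, with at most 2 higher and 2 lower identifiers where names are missing, and this rule was fixed before the data were examined. The reference gene table has 25635 rows, 0 of them with an Ensembl identifier, so 0 identifiers were matched to a symbol. The gene lists fixed before the data were examined, the 4 Hedgehog feedback targets and sex by W chromosome genes were therefore not analysed here.

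Principal components and Pearson correlations were computed on log2(value + 1) of the tested genes. Measures per library were compared with two-sided exact permutation tests over the 126 ways to choose 4 of 9 libraries. For all-or-none genes, presence was a value of at least 100 and absence a value of at most 2, limits chosen after the data had been examined. The test was run on simulated data, in which negative binomial counts had the means, library sizes and spread of the tested genes and 200 genes were changed. It made 105 calls, of which 6 were unchanged genes. With a small spread it called 199 of the 200 changed genes. Alternatives were other scalings, filters, pseudocounts and thresholds, limma without robust estimation, limma-voom on recovered reads, replicate blocks, leaving out libraries, weights per library and covariates. Figures were drawn with matplotlib 3.10.9.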

Results

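Gene expression was measured by RNA sequencing in cells taken as chick coelomic epithelium, the sheet that lines the embryonic body cavity. They came from embryos with or without a construct meant to block Hedgehog signalling. The construct was PtcDLoop2, a form of the Hedgehog receptor Patched from which a loop needed for ligand binding has been removed. Such a receptor is meant to hold the pathway off whether or not ligand is present. PtcDLoop2 was electroporated together with GFP in 5 embryos, and 4 control embryos received GFP alone. Embryos were at Hamburger-Hamilton stages 12 to 13 at electroporation and near stage 16 when they were harvested 14 h later. GFP-positive cells of each embryo were sorted and sequenced separately, so each library is a separate embryo. The 9 libraries held between 10388989 and 13517164 reads assigned to 12155 genes.

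The comparison of the PtcDLoop2 group with the control GFP group asks which transcripts of the coelomic epithelium depend on Hedgehog signalling. The 2 higher genes with the smallest p were ENSGALG00000012226 and ENSGALG00000012726, and the 2 lower genes with the smallest p were ENSGALG00000012837 and ENSGALG00000025738. These ranked 1, 2, 4 and 5 by p among all genes tested, and the gene between them was a further higher one beyond the limit of 2 identifiers per direction. The files identify genes by Ensembl number and do not pair the numbers with names, so the known Hedgehog targets, Patched itself and the markers of other cell types are not analysed here. None of the 4 genes passed the threshold of the limma test across all genes, although in each of them the values of the groups did not overlap.

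ENSGALG00000012226 had a mean normalized read count of 994.5 ± 246 (SD, n = 5) with PtcDLoop2 and 282 ± 72.3 (SD, n = 4) in the controls. Its lowest PtcDLoop2 library, at 701.5, lay above its highest control library, at 369. The log2 fold change of ENSGALG00000012226 was 1.82 ± 0.27 (SE), a 3.52-fold higher level, with limma adjusted p = 0.158 by the Benjamini-Hochberg method. ENSGALG00000012726 was among the abundant transcripts, with 12510 ± 1404 normalized counts (SD, n = 5) against 6734 ± 750.4 (SD, n = 4). Its log2 fold change was 0.89 ± 0.15 (SE), a 1.86-fold higher level, with limma adjusted p = 0.228. A quality weight per library in limma-trend, an alternative chosen after the data had been examined, brought ENSGALG00000012226 past the threshold with limma adjusted p = 0.0204 and left the other 3 genes short of it. The planned limma-voom fit with library quality weights did not call ENSGALG00000012226, with limma adjusted p = 0.0672.

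ENSGALG00000012837 had 781.5 ± 291 normalized counts (SD, n = 5) with PtcDLoop2 and 2198 ± 490 (SD, n = 4) in the controls. Its log2 fold change was -1.53 ± 0.27 (SE), a 2.88-fold lower level, with limma adjusted p = 0.238. The ranges came close, since PtcDLoop2 replicate 3 reached 1265 and control replicate 3 was at 1474. ENSGALG00000025738 had 139 ± 35.1 normalized counts (SD, n = 5) against 440.2 ± 79.6 (SD, n = 4). Its log2 fold change was -1.68 ± 0.31 (SE), a 3.2-fold lower level, with limma adjusted p = 0.255. Each of these 4 differences was larger than the spread between replicates of either group, which follows in part from picking genes by their p.

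**Figure D1:**
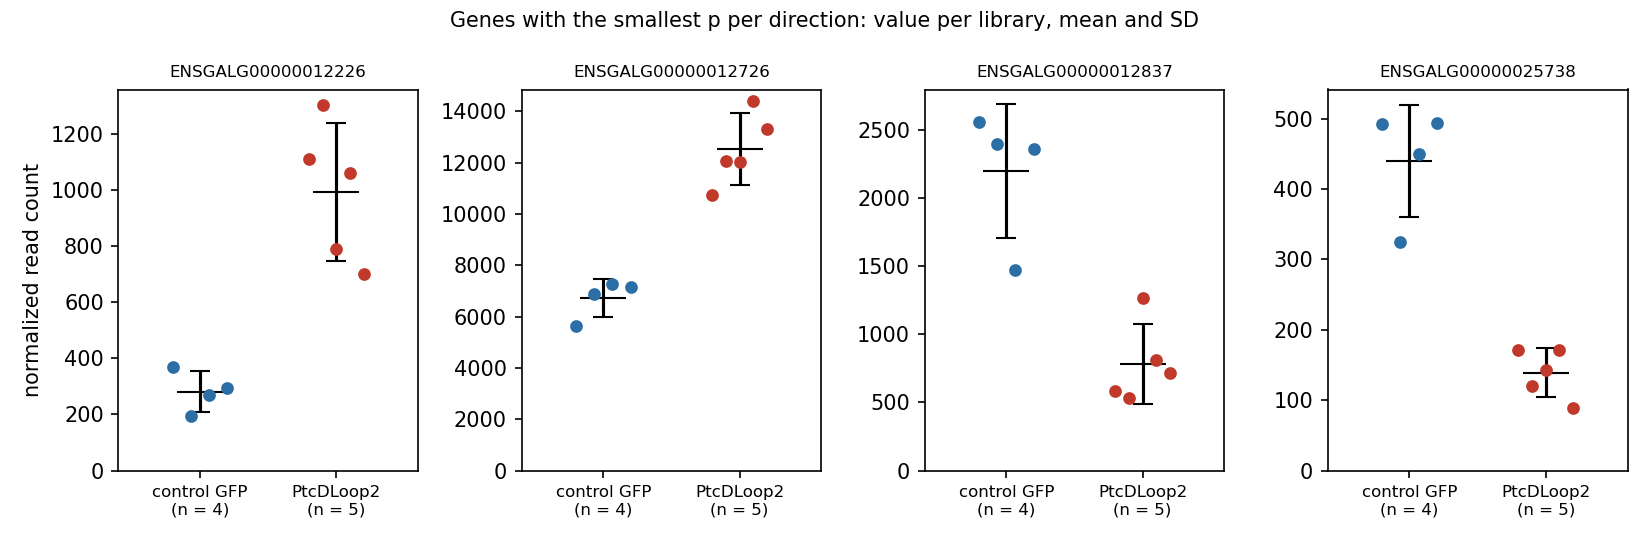
Normalized read count of the 4 named genes in every library (vertical axes, linear from 0), with control GFP embryos in blue (n = 4) and PtcDLoop2 embryos in red (n = 5). Bars give the mean and SD of each group. ENSGALG00000012226 lies between 701.5 and 1304 with PtcDLoop2 and between 193 and 369 in the controls, and in none of the 4 genes do the groups overlap.

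Across the 9621 genes tested with limma-trend, 0 genes had a Benjamini-Hochberg adjusted p under 0.05, 0 of them higher and 0 lower, and the smallest adjusted p was 0.158. At an unadjusted p under 0.05 there were 459 genes, 193 higher and 266 lower with PtcDLoop2, where 481 would be reached by chance. Limma-voom on the recovered whole reads also called 0 genes, with 451 at an unadjusted p under 0.05, and with library quality weights 0 genes and 557. The groups did not overlap in 145 genes, 46 higher and 99 lower, against 153 by chance at a share of 1.59%. In simulated data with the spread of these libraries, the same limma-trend test on 9621 genes recovered 12% of the genes changed 2-fold, 44% at 4-fold, 70% at 8-fold and 72% at 16-fold. A change of 2-fold was therefore mostly not detectable with these embryos. In that simulation 50 genes were changed at each of these fold changes together, and 105 genes were called. The Benjamini-Hochberg method asks for a smaller unadjusted p where few genes pass than where many do. If few genes changed in these embryos, the simulated rates therefore overstate the power of this comparison.

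The authors' deposited table of the same comparison lists 13 genes with an adjusted p under 0.05, of which 7 were higher and 6 lower with PtcDLoop2. It marks 12 genes as stringent and 5 more as permissive, and these 17 genes are those with an adjusted p under 0.1. Of its 12150 genes with a p-value, 694 or 5.71% had an unadjusted p under 0.05, close to the share that chance gives. This share says nothing about the 13 calls, which are too few to move it. In the authors' deposited table ENSGALG00000012226 has an adjusted p of 1.36e-06, ENSGALG00000012726 of 0.000362, ENSGALG00000012837 of 0.00186 and ENSGALG00000025738 of 3.64e-05. The absolute log2 fold changes of the 13 genes in the authors' deposited table run from 0.89 to 6.29. The filter on low values left 12 of the 13 for limma, where all 12 had the direction of the authors' deposited table and 11 were among the 25 genes with the smallest p. In 10 of the 13 genes the values of the groups did not overlap. Across the 9621 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of limma had r = 0.881. Both were computed from the same libraries, so the shared directions, ranks and r are no independent support for the 13 calls.

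No separation of the groups was seen across the transcriptome as a whole. The mean correlation of log2 values across genes was 0.859 over the 16 pairs of libraries within a group and 0.853 over the 20 pairs between groups (one-sided exact permutation p = 0.262 over 126 splits). The first principal component, with 26.1% of the variance, set PtcDLoop2 replicate 1 apart at a score of -138.6 from the other libraries, which lay between -8.95 and 46.1. The second, with 21.6%, set control replicate 4 apart at -127.9. The same libraries had the fewest detected genes, 10074 in PtcDLoop2 replicate 1 and 10303 in control replicate 4, against 10742 to 11697 in the rest. The 10 most abundant genes took between 11.4% of the normalized counts, in PtcDLoop2 replicate 5, and 33.3%, in control replicate 4. No difference between the groups passed the test in reads, detected genes, the share of the 10 most abundant genes, the mean correlation with other libraries or the first 3 components (two-sided exact permutation tests, 7 measures, smallest p = 0.143, adjusted p = 0.889). Without these 2 libraries, an alternative chosen after the data had been examined, limma called 5 genes, all 5 lower with PtcDLoop2. None of the 5 was among the 4 named genes or among the 13 genes of the authors' deposited table.

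A set of 12 genes was present at 101.7 or more normalized counts in 4 libraries and at 1.6 or less in the other 5. The 4 libraries were PtcDLoop2 replicate 3 and control replicates 1, 2 and 4, which is 1 of 5 PtcDLoop2 embryos and 3 of 4 control embryos (two-sided Fisher's exact p = 0.206). ENSGALG00000012837 had its highest PtcDLoop2 value in a library with these genes and its lowest control value in the control library without them. With presence of the 12 genes as a covariate, also an alternative chosen after the data had been examined, the log2 fold change of ENSGALG00000012837 was -1.06. Those of ENSGALG00000012226, ENSGALG00000012726 and ENSGALG00000025738 were 1.72, 0.84 and -1.67, close to their values without the covariate. In that fit 0 genes passed the limma threshold. At an unadjusted p under 0.05 there were 100 genes, well below the 481 expected by chance. The low count therefore does not show that the covariate accounted for differences between the groups.

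**Figure D2:**
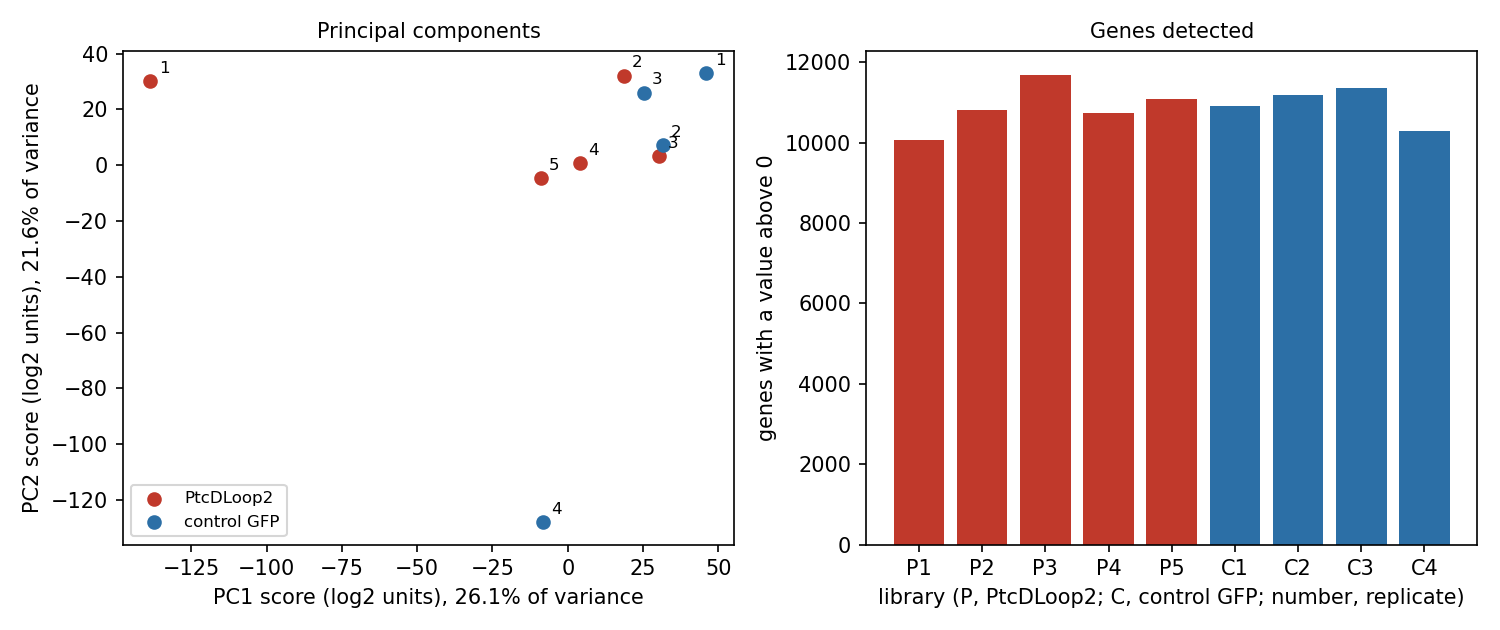
Left, scores of the 9 libraries on the first and second principal components of log2 values (horizontal and vertical axes, log2 units), with replicate numbers beside the points. Right, number of genes with a value above 0 (vertical axis) in each library (horizontal axis). PtcDLoop2 embryos are red and control GFP embryos blue, and PtcDLoop2 replicate 1 with 10074 genes and control replicate 4 with 10303 genes stand apart on the first and second component, respectively, and have the fewest detected genes.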

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

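The test of the direction of deviating genes was chosen after the result had been seen. Highest and lowest values were examined in 22 groups of library measures and named genes, where chance alone marks about 1 in 20 groups. Of these, 2 were marked, and both are scores on principal components. Such components are built from these libraries to give the largest spread, so the chance rate does not hold for them. The score of PtcDLoop2 replicate 1 on the first principal component, -138.6, lay far from the other 4 libraries of its group, between -8.95 and 30.3. The score of control replicate 4 on the second component, -127.9, lay far from the other 3 controls, between 7.29 and 32.9.

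PtcDLoop2 replicate 1 and control replicate 4, the libraries with the fewest detected genes, differed from the rest mainly by genes with lower values. In PtcDLoop2 replicate 1, 888 genes lay more than 3 log2 units below the median of the other libraries and 92 above it, and in control replicate 4 these numbers were 692 and 71. The lower share of deviating genes that lay below was 90.6%, but these libraries were picked for their few detected genes and the share was over 75% in 6 of the 9 libraries, so loss of transcripts as against another source cannot be told apart by it. RNA of a cell type that the other libraries lack also stays open: 6 abundant genes in PtcDLoop2 replicate 1 and 0 in control replicate 4 exceeded 8 times the highest other library, and the bound set before the result, no more than in any other library, was met only by a tie with control replicate 1, which had 6 and is itself not known to be free of other cells. Cell numbers were not used here, and no other biological explanation of these 2 libraries was tested.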

How the results depend on the processing

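The 2-library omission, weights per library in limma-trend, unweighted voom, trimmed mean of M-values, the block of numbers 1 and 2 and both covariates were chosen after seeing the data, and the rest were planned. Of 27 alternatives that refitted the model, 25 gave 0 genes past the threshold; 3 others changed only the threshold and, with a smallest adjusted p of 0.158, had to give 0. Without the 2 libraries with the fewest detected genes, 5 genes passed, 0 higher and 5 lower, and with library quality weights in limma-trend 1 gene passed, 1 higher and 0 lower; the cause was not tested. Leaving out each library in turn gave 0 genes each time, with a smallest limma adjusted p between 0.0793 and 0.779. Of the 4 named genes, none changed direction. Over the alternatives the log2 fold change of ENSGALG00000012226 ran from 1.65 to 1.97 (limma adjusted p from 0.0204 to 1.00), of ENSGALG00000012726 from 0.81 to 0.98, of ENSGALG00000012837 from -1.72 to -1.06 and of ENSGALG00000025738 from -1.82 to -1.52. A replicate block by title number, by description number or of title numbers 1 and 2 against the rest gave 0 genes. The block by title number leaves PtcDLoop2 replicate 5 without a partner, and that by description number used only 6 libraries. Both had little power, with a smallest limma adjusted p of 0.936 by title number and 0.995 by description number. Their 0 genes, counted among the 25 above, therefore say little. Pairs of libraries with the same number did not deviate together (correlations of residuals from -0.07 to 0.06), and 1 of 8 libraries by title number and 1 of 6 by description number correlated best with its own number. No scaling moved the median log2 fold change of all genes by over 0.1. DESeq2, edgeR, sva, a covariate from W chromosome genes and the tests of gene lists were not run. Between 3.77% and 17.1% of genes were at 0 in a library, and whether this follows depth was not tested.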

Other observations

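The tests of other splits, of overlap among the authors' calls and of depth and description numbers were chosen after the results had been seen. The tests of embryo sex, of gene dosage and of the influence of single libraries on overlapping genes were set before their results were seen.

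A set of 12 genes was all-or-none across embryos, with a median of 277 normalized counts where present, and the split crossed the groups. The 4 libraries with them were PtcDLoop2 replicate 3 and control replicates 1, 2 and 4. Loss of transcripts at low depth is argued against, since the highest loss rate of any of the 5 other libraries gives 1.65e-11 such genes by chance, and a batch by description number is argued against by 2 numbers found on both sides. Sex of the embryo, with genes of the female-specific W chromosome, is a candidate explanation that stays open, since the files pair no identifier with a chromosome: of 11 further genes that differed between the 2 kinds of library (limma adjusted p under 0.05, group in the model), 0% were higher in the libraries lacking the set, but 10 of the 11 were themselves nearly absent there, so this test repeated the pattern. Among 4592 genes at 100 or more in every library, 75 were 1.2 to 2.2 times higher in those 5 libraries without overlap, where the median split gave 27, but 8 of the 126 splits gave as many and the highest other gave 141, which meets the bound set beforehand against gene dosage. Dosage sets no limit on what other splits give, though, so that bound was badly chosen and dosage was neither excluded nor shown.

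The real split gave 0 genes past the limma threshold, a number that any split reaches (100 of the 100 drawn), so this count says nothing about chance. The highest other split gave 40 genes, which points to a structure of the samples. It follows the 12 all-or-none genes, and genes absent from the same libraries favour it by construction. It also differs from the real split only by the exchange of PtcDLoop2 replicate 3 and control replicate 3, so the count does not show a structure separate from the treatment. For genes at an unadjusted p under 0.05, 29 of the 100 drawn splits gave at least the 459 of the real split, and the highest other gave 1302, so chance could not be excluded. For genes without overlap, 52 of all 126 splits gave at least the real 145, and the highest other gave 626. The split with 1302 and 626 genes was PtcDLoop2 replicates 1 and 2 and control replicates 1 and 2 against the rest, which crosses the groups. This split was picked as the highest and gave 0 genes past the limma threshold, so a second structure is possible but not shown. The split follows the order of the title numbers, so a batch by order of processing is possible. Description number 7 is found on both sides, in PtcDLoop2 replicate 2 and control replicate 3, which argues against a batch by description number. The labels do not say that either kind of number marks an order or a day. A batch by order of processing stays open. With that split as a block, an alternative chosen after it was seen, limma called 0 genes between the groups and 524 were at an unadjusted p under 0.05.

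The authors' deposited table calls 13 genes that limma does not call at an adjusted p under 0.05. In 10 of the 13 genes the groups did not overlap, so the direction of these 10 did not rest on a single library. The 13 genes were picked by small p in the same libraries, which favours groups without overlap. In the other 3, leaving out the most influential library kept at least 77.1% of the log2 fold change. For low genes the size of the change depended on the scale, in either direction. The log scale used here gave 3.68 for ENSGALG00000012108 against 6.29 in the authors' deposited table. For ENSGALG00000002816 it gave the larger change, -5.13 against -4.55. The authors' test was not repeated without single libraries. Whether a single deviating library decided any of these calls therefore stays open. The difference between the test behind the authors' deposited table and limma-trend, and the effect of the Hedgehog block, both stay open and were not tested apart, since the count test was not run here.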
